A study of Mus musculus with 10 samples.

How the data were processed

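The deposited values are raw counts per gene, and per the submitters' processing notes the authors trimmed reads with Trimmomatic 0.36, aligned them to mm10 with HISAT2, handled alignments with SAMtools and counted reads with featureCounts of Subread 1.5.1. The gene annotation, the strand setting, the treatment of multiply mapped reads, the doses and the treatment lengths are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical copies are uncertain. Total RNA (2 ug) was extracted with TRIzol and made into polyadenylated RNA libraries with a TruSeq kit. The table held 21513 gene symbols with none blank or repeated, for 10 libraries. Actc1, Tnnc1, Pln and Cpt1b were not analysed here.

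Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3), filtered with filterByExpr to 15740 genes, and fitted with all 5 groups in 1 quasi-likelihood model, whose p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison and called at 0.05. Every adjusted p of a gene comes from edgeR unless another tool is named, and every adjusted p of a list from camera (limma 3.58.1). Standard errors are the absolute log2 change over the square root of F. Where a group had no counts, the fold is a lower bound from a floor of 3 counts, and such bounds and counting intervals cover counting error only. Lists were 35 sets of gene symbols written before the data were examined, tested by camera with a preset correlation of 0.01 when at least 5 genes were tested (34 lists), with a test under an estimated correlation and fry beside it. Named genes followed a rule: the 6 study genes, then up to 6 largest rises and 6 largest falls among called genes with CPM ranges that did not overlap and at least 5 CPM in the higher group, leaving out predicted and clone names, then up to 4 called members of a list with the smallest p. Some genes that met the rule are not reported here. Log2 CPM for the axis used a prior count of 2.

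Replicates of a group had Pearson correlations of log2 CPM of 0.984 in CF, 0.993 in iCM with DMSO, 0.992 with ZLN005, 0.991 with GW501516 and 0.991 in CM. Their chi-square per degree of freedom was 61.2, 6.53, 4.24, 3.41 and 5.60 in the same order, so CF replicates differed most. The first 2 principal components held 54.8 and 28.1 percent of the variance.

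The method was run on simulated counts in which 200 genes were changed, 50 each by 1.5, 2, 4 and 8 times. For iCM with DMSO against CF (15555 genes) 64, 76, 98 and 100 percent were called, and 6.11 percent of calls were false. For ZLN005 against DMSO (15539 genes) the values were 64, 86, 96 and 98 percent with 7.53 percent false, for GW501516 against DMSO (15562 genes) 74, 88, 96 and 100 percent with 8.21 percent false, for ZLN005 against GW501516 (15554 genes) 62, 82, 94 and 100 percent with 6.63 percent false, and for CM against ZLN005 (15377 genes) 66, 82, 98 and 100 percent with 3.89 percent false. False calls thus exceeded the nominal 5 percent in 4 of these 5 comparisons. Each value comes from a single simulated data set without an interval, so small excesses are uncertain. A raised list was called each time and 0 of 33 unchanged lists were. These lists were random genes with independent noise, so false calls from correlated genes could not arise there. Of the results for the real lists, 99 of 204 were weaker with an estimated correlation. Libraries placed at 30 and 60 percent of the axis were returned at 30.0 and 59.9 percent. They were built on the axis itself with added noise, so this checks the calculation and not libraries that lie off the axis.

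Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, DESeq2 size factors, other filters, only the groups compared, a block for replicate number, other prior counts and thresholds, and leaving out each library. Chosen only after the data were seen were a fit of the 3 iCM groups alone, results with the macrophage list and 854 other genes at least 1 log2 unit higher in CF replicate 1 than in CF replicate 2 left out (the CF replicate 1 set), and leaving out CF replicates in comparisons without CF. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.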

Results

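Polyadenylated RNA from neonatal mouse heart cells was sequenced in 10 libraries, which form 5 groups of 2. Cardiac fibroblasts (CF) were taken at day 14. Induced cardiomyocyte-like cells (iCM), labelled MGT for the cardiac transcription factors Mef2c, Gata4 and Tbx5, were taken at day 14 of reprogramming after dimethyl sulfoxide (DMSO, the solvent control), ZLN005 (an activator of Ppargc1a transcription) or GW501516 (an agonist of the nuclear receptor PPARδ). Primary cardiomyocytes (CM) were taken at day 3, so the day differed together with the cell type in every comparison with CM. The titles and library names call these last samples cardiomyocytes while 2 other label fields repeat the fibroblast entries. The titles were used, and Myh6, the alpha myosin heavy chain of cardiac muscle, stood at 9647 ± 7.3 CPM (counts of a gene scaled to the library total) in these libraries against 40.2 ± 1.7 in CF (SD, n = 2). Total counts were 61016247 and 61886463 in CF, 53395818 and 49247770 in iCM with DMSO, 39065969 and 56923512 with ZLN005, 41843624 and 40290880 with GW501516, and 46978740 and 40664504 in CM. Values below are mean CPM ± SD of the 2 libraries of a group (n = 2), and log2 changes ± their standard error with adjusted p from edgeR. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries.

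The study's title concerns Scd1, a desaturase of stearoyl-CoA, and PGC1α, the mitochondrial coactivator encoded by Ppargc1a. On GRCm38 (mm10), Scd1 lies on chromosome 19 from 44394455 to 44407879, Ppargc1a on chromosome 5 from 51454250 to 51567726, and Ppard, the gene of PPARδ, on chromosome 17 from 28232700 to 28301474. Of the 3 reprogramming factors, Mef2c lies on chromosome 13 from 83504034 to 83667080, Gata4 on chromosome 14 from 63198922 to 63271692 and Tbx5 on chromosome 5 from 119832668 to 119885219. Ppargc1a stood at 2.10 ± 0.097 CPM in CF, 2.18 ± 0.27 in iCM with DMSO, 4.02 ± 0.48 with ZLN005, 2.83 ± 0.79 with GW501516 and 51.4 ± 4.8 in CM. Scd1 stood at 110 ± 9.7, 73.3 ± 1.6, 79.5 ± 2.6, 130 ± 0.066 and 115 ± 7.7 CPM in the same order.

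**Figure D1:**
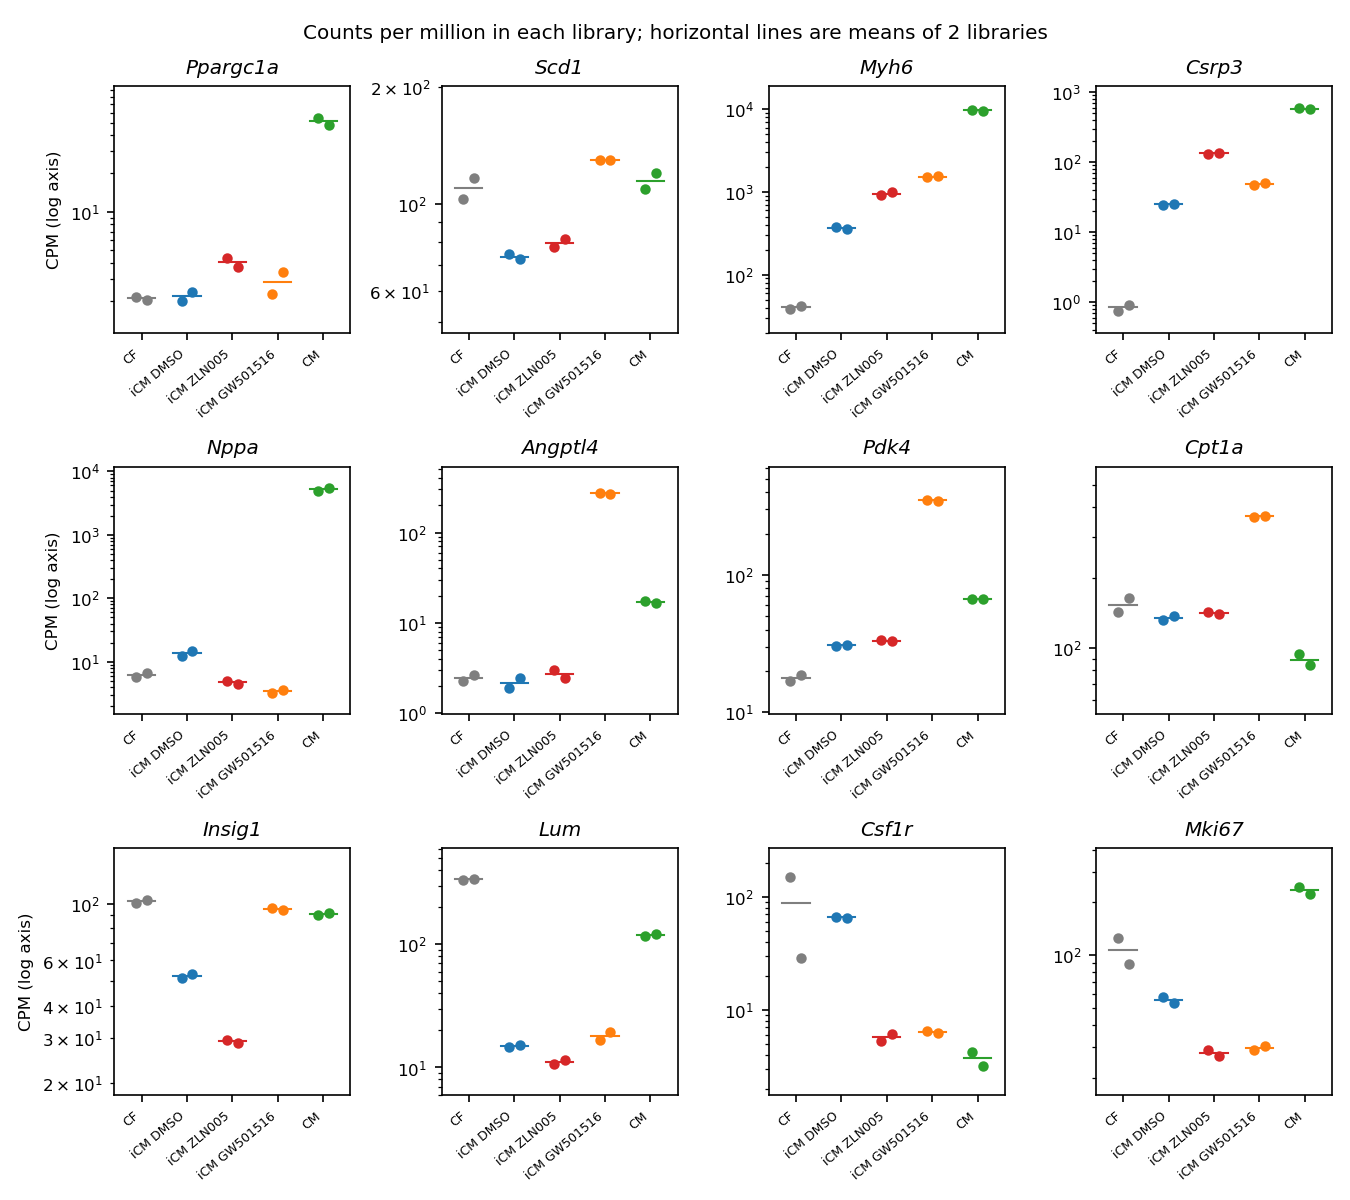
CPM (log axis) of 12 genes in each of the 10 libraries, grouped as CF, iCM with DMSO, ZLN005 or GW501516, and CM; points are libraries and horizontal lines are means of 2 libraries. Ppargc1a had a mean of 4.02 CPM with ZLN005 against 51.4 in CM, Angptl4 a mean of 273 CPM with GW501516 against 2.17 with DMSO, and the 2 CF libraries lay far apart for Csf1r, a macrophage receptor (mean 89.1, SD 85).

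The comparison of DMSO-treated iCM with CF asked how the reprogramming cells differ from fibroblasts. The CF titles name neither a vector nor DMSO. Effects of gene delivery or of the solvent therefore cannot be told apart from those of the factors in this comparison. Genes of the contractile apparatus were far higher in the iCM. Myl7, an atrial myosin light chain, stood at 851 ± 47 against 4.88 ± 0.61 CPM (log2 change 7.45 ± 0.10, adjusted p = 2.5e-12). Myom2, an M-band protein, stood at 366 ± 8.0 against 3.03 ± 0.37 (6.92 ± 0.07, adjusted p = 1.1e-12), and Sln, which encodes the calcium pump regulator sarcolipin, at 195 ± 7.6 against 0.451 ± 0.059 (8.75 ± 0.09, adjusted p = 9.1e-13). The 3 factors themselves rose, Tbx5 by 7.44 ± 0.07, Mef2c by 2.30 ± 0.08 and Gata4 by 1.28 ± 0.05 on the log2 scale, with counts that do not separate the endogenous genes from the transgenes. Of the 36 tested genes of the cardiac sarcomere and Z-disc, 32 rose and 2 fell (32 and 2 adjusted over the list alone), with a median log2 change of 3.10 (camera adjusted p = 5.3e-116, and adjusted p = 0.00847 with an estimated correlation). Synpo2l (5.87 ± 0.07), Smpx (6.58 ± 0.08) and the thin filament capping gene Lmod2 (6.68 ± 0.08) were among them. Of 36 genes of calcium handling and excitation, 24 rose and 3 fell (25 and 4 adjusted over the list alone), with a median of 1.48 (adjusted p = 4.0e-33, and 0.0216 with an estimated correlation). Trdn, a triadin of the calcium release unit, rose by 5.55 ± 0.06 and Ryr2 (6.36 ± 0.11), the ryanodine receptor, which reached 280 ± 17 from 3.41 ± 0.61 CPM. Kcnc4, a potassium channel gene, had the largest rise among named genes (10.53 ± 0.18), followed after Sln by Rxfp1 (8.21 ± 0.10), the relaxin receptor, and Abra (7.58 ± 0.20), an actin-binding regulator. Cardiac transcription factors and natriuretic peptides moved both ways, 8 up and 3 down of 23 (8 and 4 adjusted over the list alone, list adjusted p = 0.398), with Tbx18 (1.45 ± 0.06) and Esrrg (2.57 ± 0.14) higher and Zfpm2 (−0.80 ± 0.06) and Gata6 (−0.63 ± 0.06) lower.

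Fibroblast genes went down in the same comparison. Lum, the matrix proteoglycan lumican, fell from 339 ± 3.1 to 14.8 ± 0.38 CPM (−4.51 ± 0.07, adjusted p = 8.5e-12), and Dcn, decorin, from 750 ± 3.7 to 117 ± 5.7 (−2.68 ± 0.05). Pdgfra (−2.97 ± 0.06), a PDGF receptor of fibroblasts, Fbln1 (−2.21 ± 0.05), Cygb (−4.30 ± 0.10), Dlk1 (−4.61 ± 0.32), Saa3 (−4.55 ± 0.42) and Lgi2 (−4.21 ± 0.10) also fell. Of 34 fibroblast and matrix genes 22 fell and 5 rose (23 and 5 adjusted over the list alone), with a median of −0.73 (adjusted p = 1.0e-29, but adjusted p = 0.250 with an estimated correlation). Myofibroblast and TGF-beta response genes mostly rose, 17 of 24 with 6 falls (17 and 6 adjusted over the list alone, median 0.59, adjusted p = 0.00169, but adjusted p = 0.680 with an estimated correlation). Ltbp1 rose by 3.90 ± 0.08 and Tgfb2 by 1.89 ± 0.09, and Thbs2 fell by 2.17 on the log2 scale. Cell cycle genes fell, 26 of 32 with 1 rise (26 and 1 adjusted over the list alone, median −0.78, adjusted p = 2.7e-05, but adjusted p = 0.636 with an estimated correlation). Cenpf changed by −1.41 ± 0.09 and Cdk1 by −0.84 ± 0.06. All 26 called interferon response genes of 29 rose (26 adjusted over the list alone, median 0.97, adjusted p = 2.0e-08, but adjusted p = 0.636 with an estimated correlation). Rsad2 rose by 2.56 ± 0.10. Scd1 was lower in iCM (−0.58 ± 0.07, adjusted p = 4.2e-05), as were the desaturase genes Fads2 (−1.21 ± 0.05) and Scd2 (−0.90 ± 0.05). Of the cholesterol synthesis genes 15 of 23 fell and 1 rose (16 and 1 adjusted over the list alone, median −0.42, adjusted p = 0.0261, but adjusted p = 0.680 with an estimated correlation, and adjusted p = 0.0825 without CF replicate 2). Of 26 nuclear genes of respiratory complexes II to IV, 22 rose (23 adjusted over the list alone, median 0.30, adjusted p = 0.00630, but adjusted p = 0.680 with an estimated correlation). Cycs, cytochrome c, rose by 0.58 ± 0.05. Of 25 glycolysis genes 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.00183, but adjusted p = 0.473 with an estimated correlation). Eno3 rose by 2.38 ± 0.10. Ppargc1a differed by 0.05 ± 0.19 (adjusted p = 0.85), and Ppard by −0.19 ± 0.06 (adjusted p = 0.029), a call lost without CF replicate 1 (adjusted p = 0.0775) or DMSO replicate 1 (adjusted p = 0.234).

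In all, 3126 genes were higher and 3066 lower of 15740 tested, and 12 of 34 lists were called, of which the sarcomere and calcium lists held with an estimated correlation. The 2 CF libraries differed in macrophage genes, which held 0.452 percent of the counts of CF replicate 1 (exact 95% interval 0.450 to 0.453) and 0.0946 percent of replicate 2 (0.0939 to 0.0954), on either side of the 0.165 ± 0.0034 percent in iCM with DMSO. The macrophage list, not called here (0 up and 1 down of 25, 0 and 1 adjusted over the list alone, median −0.72, adjusted p = 0.578), was called in opposite directions when 1 CF library was left out, higher in iCM without CF replicate 1 (20 up and 1 down, median 1.02, adjusted p = 8.2e-05) and lower without CF replicate 2 (1 up and 22 down, median −1.49, adjusted p = 8.6e-17). Mmp9, a protease of neutrophils and macrophages, was lower by −6.02 ± 1.54, from 10.2 ± 14 CPM in CF, and its log2 change was −0.34 (adjusted p = 0.777) without CF replicate 1, −5.96 (adjusted p = 0.0835) without DMSO replicate 1 and −6.08 (adjusted p = 0.0779) without DMSO replicate 2.

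ZLN005 was compared with DMSO in iCM to ask what an activator of Ppargc1a transcription adds to reprogramming. Ppargc1a rose from 2.18 ± 0.27 to 4.02 ± 0.48 CPM (0.87 ± 0.18, adjusted p = 0.0096), a call lost without DMSO replicate 1 (0.76, adjusted p = 0.0932), without ZLN005 replicate 1 (0.76, adjusted p = 0.0831) and with limma-voom (0.86, adjusted p = 0.0513). Scd1 stood at 79.5 ± 2.6 against 73.3 ± 1.6 CPM (0.12 ± 0.07, adjusted p = 0.28), Ppard differed by 0.09 ± 0.06, Mef2c by 0.07 ± 0.07 and Tbx5 by 0.10 ± 0.05 with none called. The Tbx5 difference was called without CF replicate 1 (adjusted p = 0.0482) or CF replicate 2 (adjusted p = 0.0489). Gata4 rose by 0.29 ± 0.05 (adjusted p = 0.0041, and 0.0526 without ZLN005 replicate 2). Contractile genes rose: Csrp3, the Z-disc protein MLP, went from 24.97 ± 0.28 to 133 ± 0.27 CPM (2.41 ± 0.06, adjusted p = 7.3e-09), Myh6 from 365 ± 11 to 957 ± 56 (1.39 ± 0.06, adjusted p = 5.1e-07) and Actn2, the Z-disc alpha-actinin, from 65.3 ± 1.7 to 138 ± 1.4 (1.08 ± 0.04). The sarcomere list had 26 rises and 3 falls of 36 (26 and 4 adjusted over the list alone) and a median of 0.62. That call held with an estimated correlation (adjusted p = 2.3e-45, and 0.0396). Calcium handling genes had 14 rises and 4 falls of 36 (18 and 4 adjusted over the list alone, median 0.45, adjusted p = 1.2e-12, but adjusted p = 0.0731 with an estimated correlation). Popdc2 rose by 1.19 ± 0.07 and Atp2a2, the calcium pump SERCA2, by 0.74 ± 0.05 to 2487 ± 13 CPM. Esrrg, a nuclear receptor that acts with PGC1α, rose by 1.53 ± 0.11 to 6.81 ± 0.068 CPM, while Nppa, the atrial natriuretic peptide, fell from 13.6 ± 1.8 to 4.73 ± 0.45 CPM (−1.53 ± 0.12). Their list had 6 rises and 3 falls of 23 (8 and 4 adjusted over the list alone, adjusted p = 0.344), a median of 0.10 and a mean of −0.16. Myl1 (2.21 ± 0.07) and Myh8 (2.46 ± 0.24), myosin genes of developing and skeletal muscle, and the immediate early gene Fos (2.38 ± 0.15) were among the largest rises. So were Tpm3-rs7 (2.55 ± 0.06) and Rpl26 (2.16 ± 0.08), whose reads may be shared with near-identical paralogs or processed copies, so their values are uncertain.

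With ZLN005, 16 of 26 nuclear genes of respiratory complexes II to IV rose and 1 fell (20 and 1 adjusted over the list alone, median 0.22, adjusted p = 1.4e-07, but adjusted p = 0.251 with an estimated correlation). Cox8a, a cytochrome c oxidase subunit, rose by 0.29 ± 0.04. Complex I had 8 rises of 36 (13 adjusted over the list alone, median 0.20, adjusted p = 2.5e-05, but adjusted p = 0.348 with an estimated correlation). ATP synthase had 8 rises of 16 (11 adjusted over the list alone, median 0.20, adjusted p = 0.000349, but adjusted p = 0.301 with an estimated correlation). Fatty acid oxidation genes had 8 rises and 1 fall of 27 (9 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.000104, but adjusted p = 0.223 with an estimated correlation). Acaa2, a thiolase, went from 65.7 ± 2.2 to 132 ± 0.56 CPM (1.01 ± 0.04) and Fabp3 rose as well (0.84 ± 0.07). Mitochondrial biogenesis and dynamics genes had 6 rises of 28 (6 adjusted over the list alone, median 0.05, adjusted p = 0.0202, but adjusted p = 0.224 with an estimated correlation). Mfn2, a mitochondrial fusion gene, rose by 0.31 ± 0.05. The tricarboxylic acid cycle list had 8 rises and 1 fall of 26 (11 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.000734, but adjusted p = 0.251 with an estimated correlation). Got1 rose by 0.34 ± 0.04. Glycolysis had 15 rises of 25 (16 adjusted over the list alone, median 0.30, adjusted p = 9.7e-12, but adjusted p = 0.0558 with an estimated correlation). The lactate transporter gene Slc16a1 rose by 1.01 ± 0.04. The mitochondrially encoded list went the other way without a list call (4 falls of 13, 4 adjusted over the list alone, median −0.08, adjusted p = 0.0939, and 0.0156 without ZLN005 replicate 2). COX3 fell by −0.45 ± 0.08, ATP6 by −0.45 ± 0.10, COX2 by −0.24 ± 0.07 and CYTB by −0.26 ± 0.08. These calls were lost without ZLN005 replicate 1 (adjusted p = 0.0672, 0.0997, 0.256 and 0.250). Without DMSO replicate 1 COX3, COX2 and CYTB lost theirs (0.0623, 0.253 and 0.109), without DMSO replicate 2 ATP6, COX2 and CYTB (0.0902, 0.0529 and 0.208), and without ZLN005 replicate 2 CYTB (0.113). COX3, ATP6 and COX2 share over 95 percent of their 75-base windows with nuclear copies on chromosome 1, so their counts are uncertain.

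Cholesterol synthesis genes fell with ZLN005. Fdft1, squalene synthase, went from 37.6 ± 0.63 to 18.8 ± 0.96 (−1.003 ± 0.056), and Insig1 and Msmo1 changed by −0.84 ± 0.04 and −0.83 ± 0.06. All 18 called genes of the 23 fell (18 adjusted over the list alone), with a median of −0.59. That call held with an estimated correlation (adjusted p = 6.0e-31, and 0.0396). Fatty acid synthesis and desaturation genes had 8 falls and 2 rises of 20 (9 and 2 adjusted over the list alone, median −0.26, adjusted p = 0.00200, but adjusted p = 0.0908 with an estimated correlation). Scd2 (−0.66 ± 0.05), Fads1 (−0.55 ± 0.05) and Fads2 (−0.63 ± 0.05) fell and Gpam, an acyltransferase of glycerolipid synthesis, rose by 0.54 ± 0.05. Targets of the aryl hydrocarbon receptor fell as well: Cyp1b1 went from 78.6 ± 0.64 to 16.3 ± 0.022 CPM (−2.27 ± 0.07, adjusted p = 3.6e-08), Ahrr by −2.07 ± 0.26, and Cyp1a1 had 2 counts against 60, a ratio of 28.7 with a counting interval of 7.60 to 242. That list had 3 falls and 1 rise, Xdh (0.26 ± 0.04), of 9 (4 and 1 adjusted over the list alone, median −0.32, adjusted p = 2.4e-06, and 0.0414 with an estimated correlation). Cell cycle genes fell, 24 of 32 (28 adjusted over the list alone, median −0.42, adjusted p = 2.2e-12, but adjusted p = 0.140 with an estimated correlation). The proliferation marker Mki67 fell from 55.5 ± 3.3 to 27.9 ± 1.6 CPM. Of 29 interferon response genes 15 rose (18 up and 1 down adjusted over the list alone, median 0.34, adjusted p = 2.9e-07, but adjusted p = 0.301 with an estimated correlation). Irf7 rose by 0.78 ± 0.11. PPAR targets had 6 rises and 3 falls of 30 (8 and 5 adjusted over the list alone), a median of 0.11 (also 0.11 with such genes at their bound where a group had no counts), a mean of −0.05 and a test for a rise (adjusted p = 0.00999, but adjusted p = 0.223 with an estimated correlation). Cidea rose by 1.91 ± 0.19 and Cd36 down by −1.12 ± 0.19.

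With ZLN005, 23 of 34 fibroblast and matrix genes fell and 2 rose (25 and 3 adjusted over the list alone, median −0.45, adjusted p = 1.1e-30, but adjusted p = 0.0908 with an estimated correlation). Mfap5 (−1.61 ± 0.09), Fbln2 (−0.98 ± 0.06) and Fbln1 (−0.96 ± 0.05), all microfibril or fibulin genes, fell. Of 24 myofibroblast and TGF-beta response genes 13 fell and 3 rose (13 and 4 adjusted over the list alone, median −0.32, adjusted p = 1.2e-09, but adjusted p = 0.223 with an estimated correlation). Tgfbi changed by −2.04 ± 0.09 and Cthrc1 by −1.45 ± 0.07. Of 25 macrophage and leukocyte genes 20 fell (21 adjusted over the list alone), with a median of −2.72 (adjusted p = 2.7e-12, but adjusted p = 0.228 with an estimated correlation). Spp1, osteopontin, went from 185 ± 2.4 to 33.4 ± 1.7 CPM (−2.47 ± 0.33, adjusted p = 0.00082) and Tifab from 5.50 ± 0.72 to 0.160 ± 0.016 (−5.07 ± 0.81, adjusted p = 0.0023). The macrophage list held 0.165 ± 0.0034 percent of the counts with DMSO and 0.0597 ± 0.0013 percent with ZLN005. Nxpe5 (−5.99 ± 1.37), Fcrls (−5.53 ± 0.98), Il21r (−5.18 ± 1.02) and the macrophage mannose receptor gene Mrc1 (−5.05 ± 1.13) had large falls. Their calls were lost without ZLN005 replicate 1 and also without replicate 2, so the loss does not single out either library. Nxpe5 and Mrc1 also lost their calls without DMSO replicate 1 or replicate 2. Limma-voom called none of these 4 genes or Tifab, with adjusted p from 0.165 for Tifab to 0.609 for Nxpe5. The CF libraries are outside this comparison but enter the shared estimate of the spread. Nxpe5, Fcrls, Il21r and Mrc1 stood 4.25, 3.41, 3.41 and 3.89 log2 units higher in CF replicate 1 than in CF replicate 2. In the fit of the 3 iCM groups alone, chosen after the data were seen, 0 of 373 results for named genes lost a call.

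With ZLN005, 1045 genes were higher and 1392 lower than with DMSO, and 26 lists were called, of which the sarcomere, cholesterol and aryl hydrocarbon receptor lists held with an estimated correlation. The count of 2437 genes depended on which libraries set the spread: it was 4257 without CF replicate 1 and 4245 without CF replicate 2, neither of which is in this comparison, and 1246, 1227, 1102 and 1086 without DMSO replicate 1, DMSO replicate 2, ZLN005 replicate 1 and ZLN005 replicate 2. It was 2143 with a set of genes left out that comprises the macrophage list and 854 other genes at least 1 log2 unit higher in CF replicate 1 than in CF replicate 2, below called the CF replicate 1 set, which also holds genes of other cell types such as the endothelial genes Cdh5 and Kdr, which were chosen after their values were seen. With an absolute log2 change of at least 1 added, 106 genes were higher and 441 lower, and limma-voom called 1050 higher and 1034 lower, so the excess of falls depended on the tool. Meg3, a long RNA kept in the nucleus, changed by −1.002 ± 0.063 with ZLN005 and −0.74 ± 0.06 with GW501516. Its list of 5 nuclear RNAs, kept as a sign of RNA quality, was called lower with both (medians −0.65 and −0.12, adjusted p = 0.00138 and 0.0101, but adjusted p = 0.0890 and 0.126 with an estimated correlation), so a difference in RNA quality between the compound and DMSO libraries was not excluded.

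GW501516 was compared with DMSO in iCM to ask what a PPARδ agonist adds to reprogramming. Target genes of the PPAR receptors rose strongly. Angptl4, an inhibitor of lipoprotein lipase, went from 2.17 ± 0.41 to 273 ± 4.8 CPM (6.98 ± 0.11, adjusted p = 2.1e-10), and Pdk4, the kinase that restrains pyruvate oxidation, from 30.8 ± 0.30 to 349 ± 1.8 (3.50 ± 0.05, adjusted p = 1.1e-10). Cidea (4.64 ± 0.18), a lipid droplet protein, Slc25a34 (4.49 ± 0.29) and Dnajb13 (4.07 ± 0.46) were also among the largest rises. Of 30 PPAR targets 20 rose (22 adjusted over the list alone), with a median of 0.73 (adjusted p = 2.7e-87, and 0.000803 with an estimated correlation). Of 27 genes of fatty acid uptake and oxidation 21 rose (22 adjusted over the list alone), with a median of 0.48 (adjusted p = 6.2e-45, and 0.0120 with an estimated correlation). Acaa2 reached 284 ± 10 CPM (2.11 ± 0.04), Acadl, a long-chain acyl-CoA dehydrogenase, 264 ± 7.8 (1.67 ± 0.05), Cpt1a, the carnitine transferase that controls mitochondrial entry, 366 ± 4.0 (1.45 ± 0.07) and Ech1 87.4 ± 3.7 (1.37 ± 0.05). Scd1 rose from 73.3 ± 1.6 to 130 ± 0.066 CPM (0.83 ± 0.07, adjusted p = 2.8e-05). So did 9 of 20 genes of fatty acid synthesis and desaturation (12 adjusted over the list alone, median 0.20, adjusted p = 3.1e-11, and 0.0120 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, rose by 2.02 ± 0.07 and Scd2 by 0.69 ± 0.05. Cholesterol synthesis genes rose, 15 of 23 (17 adjusted over the list alone, median 0.39, adjusted p = 7.3e-16, and 0.0452 with an estimated correlation). Insig1 rose by 0.87 ± 0.04, Stard4 by 0.85 ± 0.06 and Hmgcs1 by 0.59 ± 0.06. Ppargc1a stood at 2.83 ± 0.79 against 2.18 ± 0.27 CPM (0.37 ± 0.19, adjusted p = 0.24), Ppard at 35.5 ± 1.5 against 31.6 ± 1.7 (0.17 ± 0.06, adjusted p = 0.10), and Mef2c and Tbx5 differed by −0.05 ± 0.07 and 0.00 ± 0.05 without calls.

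With GW501516 Myh6 went from 365 ± 11 to 1534 ± 24 CPM (2.07 ± 0.06, adjusted p = 2.2e-08), Myom2 from 366 ± 8.0 to 728 ± 3.8 (0.99 ± 0.05), Csrp3 from 24.97 ± 0.28 to 48.8 ± 3.2 (0.97 ± 0.06) and Actn2 to 123 ± 0.19 (0.92 ± 0.04). The sarcomere list had 25 rises and 4 falls of 36 (27 and 4 adjusted over the list alone) and a median of 0.54. That call held with an estimated correlation (adjusted p = 2.9e-34, and 0.0384). Calcium handling genes had 14 rises and 4 falls of 36 (19 and 4 adjusted over the list alone, median 0.33, adjusted p = 3.9e-09, but adjusted p = 0.126 with an estimated correlation). Atp2a2 rose by 0.82 ± 0.05 and Corin, the protease that activates natriuretic peptides, by 0.95 ± 0.06. Nppa (−1.98 ± 0.13) and Nppb (−1.35 ± 0.19) fell and Srf (0.68 ± 0.08) and Esrrg (0.90 ± 0.12) rose, in a list with 6 rises and 2 falls of 23 (6 and 5 adjusted over the list alone, median −0.11, and −0.09 with such genes at their bound where a group had no counts, adjusted p = 0.601). Of 26 nuclear genes of complexes II to IV 22 rose (24 adjusted over the list alone, median 0.42, adjusted p = 8.0e-19, but adjusted p = 0.126 with an estimated correlation). Uqcrq rose by 0.58 ± 0.06 and Cycs by 0.46 ± 0.05. Complex I had 18 rises of 36 (33 adjusted over the list alone, median 0.26, adjusted p = 1.7e-09, but adjusted p = 0.279 with an estimated correlation). ATP synthase had 12 rises of 16 (14 adjusted over the list alone, median 0.30, adjusted p = 2.6e-09, but adjusted p = 0.185 with an estimated correlation). The tricarboxylic acid cycle had 17 rises with 2 falls of 26 (18 and 2 adjusted over the list alone, median 0.20, adjusted p = 6.3e-06, but adjusted p = 0.185 with an estimated correlation). Suclg1 rose by 0.49 ± 0.05 and Pcx, pyruvate carboxylase, fell by 0.54 ± 0.07 on the log2 scale. Glycolysis had 14 rises of 25 (16 adjusted over the list alone, median 0.37, adjusted p = 2.5e-10, but adjusted p = 0.0501 with an estimated correlation). Mitochondrial biogenesis and dynamics had 7 rises of 28 (9 adjusted over the list alone, median 0.09, adjusted p = 0.0130, but adjusted p = 0.194 with an estimated correlation). Ppargc1b rose by 0.90 ± 0.13. No mitochondrially encoded gene was called by edgeR (0 of 13, and 0 adjusted over the list alone, median 0.06, list adjusted p = 0.569), with COX1 at 0.20 ± 0.07 (adjusted p = 0.082). COX1 was called without CF replicate 1 (adjusted p = 1.8e-06), without CF replicate 2 (adjusted p = 2.1e-06), by DESeq2 (adjusted p = 0.000102) and by limma-voom (adjusted p = 0.0289).

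With GW501516 Mki67 fell from 55.5 ± 3.3 to 29.5 ± 1.0 CPM (−0.91 ± 0.13), with 16 falls of 32 cell cycle genes (20 adjusted over the list alone, median −0.38, adjusted p = 4.3e-08, but adjusted p = 0.214 with an estimated correlation). Cthrc1 (−1.29 ± 0.07), Tgfbi (−1.41 ± 0.09) and Ltbp2 (−1.35 ± 0.10) fell and Tagln (1.09 ± 0.10) rose among 24 myofibroblast genes with 9 falls and 5 rises (11 and 6 adjusted over the list alone, median −0.23, adjusted p = 0.000272, but adjusted p = 0.426 with an estimated correlation). Dcn (0.52 ± 0.04) and Dpt (0.95 ± 0.07), matrix genes of fibroblasts, rose and Mfap5 (−1.09 ± 0.09) and Gsn (−0.48 ± 0.04) fell, in a list with 13 falls and 6 rises of 34 (16 and 8 adjusted over the list alone, median −0.09, adjusted p = 0.00894, but adjusted p = 0.626 with an estimated correlation). Interferon response genes rose, 21 of 29 (24 adjusted over the list alone, median 0.53, adjusted p = 1.3e-17, but adjusted p = 0.185 with an estimated correlation). Irf7 rose by 1.21 ± 0.11. Of 25 macrophage genes 18 fell (21 adjusted over the list alone, median −2.40, adjusted p = 6.4e-11, but adjusted p = 0.270 with an estimated correlation). Spp1 went from 185 ± 2.4 to 43.7 ± 1.4 CPM (−2.08 ± 0.33, adjusted p = 0.0021), and Fcgr2b, an Fc receptor, from 14.5 ± 0.73 to 0.614 ± 0.088 (−4.55 ± 0.73, adjusted p = 0.0024). The macrophage list held 0.0554 ± 0.00035 percent of the counts with GW501516, against 0.165 ± 0.0034 percent with DMSO. Nxpe5 (−5.80 ± 1.39), Fcrls (−5.36 ± 0.98), Mrc1 (−4.71 ± 1.12), Cd33 (−4.58 ± 0.83) and Il21r (−4.53 ± 0.98) had large falls, with adjusted p of 0.129, 0.0693, 0.152, 0.0558 and 0.106 without GW501516 replicate 1, and of 0.144, 0.0624, 0.117, 0.0631 and 0.106 without replicate 2. Without DMSO replicate 1 those of Nxpe5, Mrc1 and Il21r were 0.0708, 0.0741 and 0.0521, and without DMSO replicate 2 those of Nxpe5 and Mrc1 were 0.0608 and 0.0645. Limma-voom called none of these 6 genes (adjusted p from 0.271 for Fcgr2b to 0.630 for Nxpe5). All 6 stood higher in CF replicate 1 than in CF replicate 2, from 2.51 log2 units for Fcgr2b to 4.25 for Nxpe5. Both CF libraries enter the shared estimate of the spread.

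With GW501516, 1228 genes were higher and 1095 lower than with DMSO, and 22 lists were called, of which the PPAR, fatty acid oxidation, fatty acid synthesis, cholesterol and sarcomere lists held with an estimated correlation. The count of 2323 genes was 4227 without CF replicate 1, 4224 without CF replicate 2, 1071 and 1192 without DMSO replicates 1 and 2, and 965 and 1058 without GW501516 replicates 1 and 2. With an absolute log2 change of at least 1 added, the balance reversed to 154 higher and 354 lower, it was 1357 and 1401 with no filter on low counts, and 1146 and 703 with limma-voom. Srp54b, a paralog of a signal recognition particle gene, had a log2 change of 3.72 ± 0.92 on 31.6 ± 28 CPM, its reads may be shared with its paralogs, and its adjusted p was 0.183, 0.0650 and 0.223 without DMSO replicate 1, DMSO replicate 2 and GW501516 replicate 1. Gata4 rose by 0.24 ± 0.05 (adjusted p = 0.013), with adjusted p = 0.0557, 0.0889, 0.0793 and 0.0931 without DMSO replicate 1, DMSO replicate 2, GW501516 replicate 1 and GW501516 replicate 2.

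**Figure D2:**
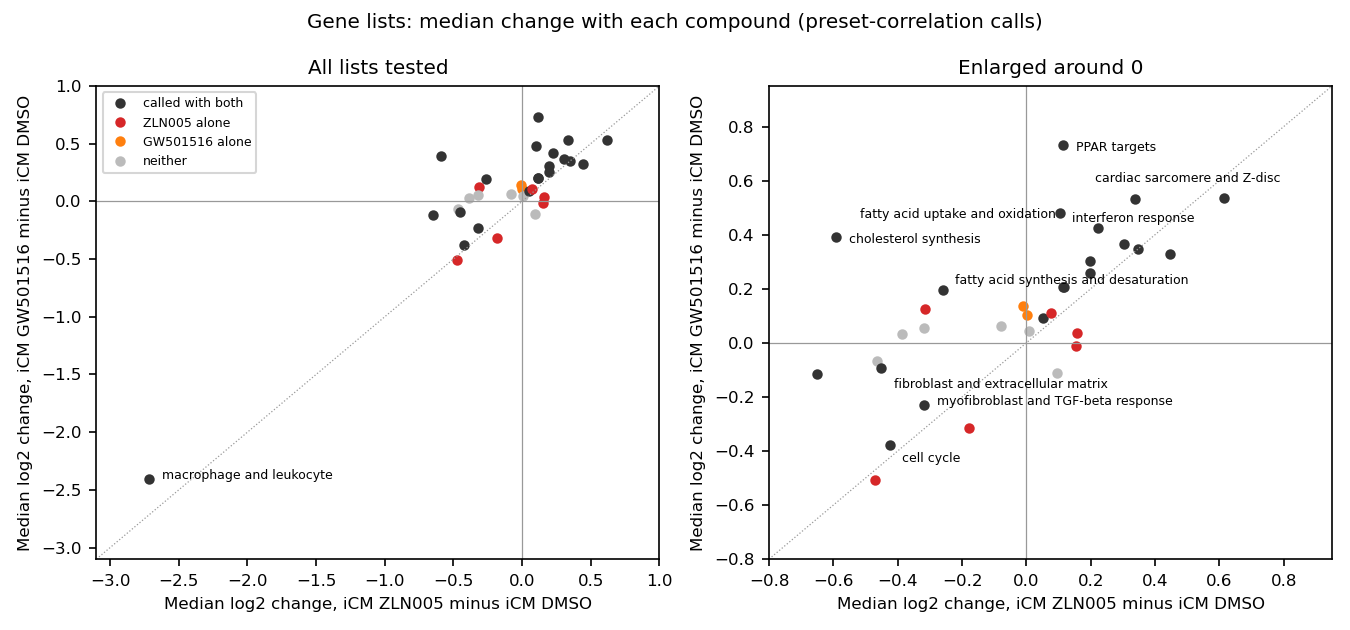
Median log2 change of each gene list with ZLN005 (x axis) and with GW501516 (y axis), each against DMSO in iCM, with the region around 0 enlarged at the right; points are lists, coloured by whether camera called them with both compounds (black), ZLN005 alone (red), GW501516 alone (orange) or neither (grey), and the dotted line marks equal change. The macrophage list lies at −2.72 and −2.40, the sarcomere list at 0.62 and 0.54, the PPAR targets at 0.11 and 0.73, and the cholesterol synthesis list at −0.59 and 0.39.

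The 2 compounds were compared directly in iCM to ask where a PGC1α activator and a PPARδ agonist differ. Scd1 was lower with ZLN005 than with GW501516 (79.5 ± 2.6 against 130 ± 0.066 CPM, −0.71 ± 0.07, adjusted p = 0.00013), and Scd2 (−1.35 ± 0.05), Fads2 (−1.27 ± 0.05), Acacb (−1.65 ± 0.07) and Fads1 (−0.89 ± 0.05) were lower as well. Of the 20 fatty acid synthesis genes 12 were lower (15 adjusted over the list alone, median −0.27, adjusted p = 2.6e-37, and 0.000660 with an estimated correlation). Of 23 cholesterol synthesis genes 20 were lower with ZLN005 (20 adjusted over the list alone, median −0.91, adjusted p = 2.2e-141, and 0.000660 with an estimated correlation). Insig1 (−1.71 ± 0.04), Fdft1 (−1.50 ± 0.06) and Msmo1 (−1.41 ± 0.06) were among them. Angptl4 stood at 2.71 ± 0.40 against 273 ± 4.8 CPM (−6.67 ± 0.11), Ucp2, a mitochondrial carrier, at 17.8 ± 1.4 against 366 ± 5.7 (−4.36 ± 0.23) and Pdk4 at 33.2 ± 0.14 against 349 ± 1.8 (−3.39 ± 0.05). Slc25a34 (−4.71 ± 0.29) and Dnajb13 (−3.48 ± 0.44) were also lower with ZLN005. PPAR targets were lower for 19 of 30 (21 adjusted over the list alone, median −0.66, and −0.55 with such genes at their bound where a group had no counts, adjusted p = 5.7e-111, and 0.000437 with an estimated correlation). Fatty acid oxidation genes were lower for 18 of 27 (21 adjusted over the list alone, median −0.42, adjusted p = 4.15e-40, and 0.00667 with an estimated correlation). Cpt1a differed by −1.38 ± 0.07. Aryl hydrocarbon receptor targets were lower with ZLN005, 4 of 9 (5 adjusted over the list alone, median −0.39, adjusted p = 7.3e-12, and 0.00610 with an estimated correlation). Cyp1b1 differed by −1.79 ± 0.07, Tiparp by −0.39 ± 0.05. Cyp1a1 had 2 counts against 38, a ratio of 23.1 with a counting interval of 5.97 to 198. The remaining called member, Xdh (−0.23 ± 0.04), lost its call without any 1 of the 4 libraries compared (adjusted p from 0.0778 to 0.0997).

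Among muscle genes, Csrp3 was higher with ZLN005 (133 ± 0.27 against 48.8 ± 3.2 CPM, 1.45 ± 0.05, adjusted p = 1.7e-07) and Myh6 lower (957 ± 56 against 1534 ± 24, −0.68 ± 0.06, adjusted p = 0.00011), as was Myh7 (−0.83 ± 0.08). The sarcomere list had 3 genes up and 3 down of 36 (6 and 4 adjusted over the list alone, median 0.07, adjusted p = 0.0490, but adjusted p = 0.702 with an estimated correlation), and its call was lost without ZLN005 replicate 1 (0.0861), GW501516 replicate 1 (0.0691) or GW501516 replicate 2 (0.0886). Calcium handling genes had 4 up and 3 down of 36 (adjusted p = 0.196), with Corin at −0.74 ± 0.06. Fst, which encodes the activin antagonist follistatin, stood at 209 ± 4.6 against 90.2 ± 1.8 CPM (1.22 ± 0.04), and Adora1 (1.67 ± 0.10), Gria1 (1.38 ± 0.20) and Tnfsf15 (1.22 ± 0.17) were higher with ZLN005. Nkain4 was higher by 1.20 ± 0.18, with 1.10 (adjusted p = 0.0534) without GW501516 replicate 1. Fibroblast genes were lower with ZLN005, 22 of 34 with 1 higher (24 and 1 adjusted over the list alone, median −0.40, adjusted p = 1.1e-28, but adjusted p = 0.146 with an estimated correlation). Fbln1 differed by −0.85 ± 0.05, Col3a1, a fibrillar collagen, by −0.67 ± 0.06 and Dcn by −0.48 ± 0.04. Nuclear genes of complexes II to IV were lower for 5 of 26 (14 adjusted over the list alone, median −0.17, adjusted p = 7.1e-06, but adjusted p = 0.565 with an estimated correlation). Ppargc1a differed by 0.50 ± 0.18 between the compounds (adjusted p = 0.18), so a difference in its response was not shown. Macrophage genes had no call between the compounds by edgeR (0 of 25, and 0 adjusted over the list alone, list adjusted p = 0.590), with 0.0597 ± 0.0013 and 0.0554 ± 0.00035 percent of the counts.

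Of the 796 genes called between the compounds 242 were higher and 554 lower with ZLN005, and 17 lists were called, of which the cholesterol, fatty acid synthesis, PPAR, fatty acid oxidation and aryl hydrocarbon receptor lists held with an estimated correlation. The count was 2163 and 2167 without CF replicates 1 and 2, 384 and 345 without ZLN005 replicates 1 and 2, and 353 and 355 without GW501516 replicates 1 and 2. With an absolute log2 change of at least 1 added, 26 were higher and 96 lower.

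The study's design asks how compound-treated iCM resemble and differ from primary cardiomyocytes, and CM was compared with each treated group. Ppargc1a was far higher in CM, by 3.68 ± 0.17 over ZLN005 (adjusted p = 2.1e-08) and by 4.18 ± 0.18 over GW501516 (adjusted p = 1.1e-08). Scd1 was higher in CM than with ZLN005 (115 ± 7.7 against 79.5 ± 2.6 CPM, 0.53 ± 0.07, adjusted p = 3.6e-05) and slightly lower than with GW501516 (−0.18 ± 0.06, adjusted p = 0.029, with adjusted p = 0.0975, 0.0954 and 0.216 without GW501516 replicate 1, GW501516 replicate 2 and CM replicate 1). The reprogramming factors were lower in CM than with ZLN005, Tbx5 by −2.42 ± 0.05, Mef2c by −1.58 ± 0.07 and Gata4 by −1.19 ± 0.05. Nppa stood at 5194 ± 294 CPM in CM against 4.73 ± 0.45 with ZLN005 (10.11 ± 0.13) and 3.45 ± 0.27 with GW501516 (10.56 ± 0.14). Myl2, the ventricular myosin light chain, stood at 1520.0 ± 9.4 against 1.28 ± 0.20 with ZLN005 (10.19 ± 0.17), and Myl3 at 726 ± 33 against 0.459 ± 0.26 (10.72 ± 0.23). Nppb was higher in CM by 9.34 ± 0.10 and 10.51 ± 0.11. Bmp10, a growth factor of trabecular and atrial myocardium, stood at 166 ± 7.8 CPM in CM and had 2 counts in each treated group, ratios of 8201 (counting interval 2270 to 67722) over ZLN005 and 6743 (1866 to 55684) over GW501516. Ckm, muscle creatine kinase, was higher by 10.96 ± 0.38 than with ZLN005 and had 12327 counts in CM against 2 with GW501516, a ratio of 5938 (1644 to 49041). Uts2b was at least 198-fold higher in CM than with ZLN005, and Irx4, a ventricular transcription factor, and Car3 at least 189.6-fold and 139-fold higher than with GW501516. Of 36 sarcomere genes 30 were higher and 2 lower in CM than with ZLN005 (30 and 2 adjusted over the list alone, median 2.20, adjusted p = 8.4e-42, but adjusted p = 0.0566 with an estimated correlation). Of the same genes 31 were higher and 2 lower than with GW501516 (32 and 2 adjusted over the list alone, median 2.58, adjusted p = 9.8e-45, and 0.0456 with an estimated correlation). Nebl, a Z-disc gene, was higher by 5.34 ± 0.08 and Mybpc3 by 4.37 ± 0.07 over the respective group. Calcium handling genes were higher for 29 and 28 of 36 with 3 lower in both comparisons (medians 1.60 and 1.85, adjusted p = 8.8e-16 and 1.1e-16, but adjusted p = 0.0661 and 0.0634 with an estimated correlation). Cacnb2, a calcium channel subunit, was higher by 4.62 ± 0.09 and 5.23 ± 0.09.

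Mitochondrial genes were higher in CM than in either treated group. All 13 mitochondrially encoded genes were higher than with ZLN005 (13 adjusted over the list alone, median 1.46, adjusted p = 1.6e-08, but adjusted p = 0.0980 with an estimated correlation). All were also higher than with GW501516 (13 adjusted over the list alone, median 1.21, adjusted p = 5.3e-07, but adjusted p = 0.172 with an estimated correlation). ND1, which has none of its 75-base windows in a nuclear transcript, stood at 7467 ± 112 against 2591 ± 161 CPM with ZLN005 (1.53 ± 0.07). These genes held 5.50 ± 0.049 percent of the counts of CM, 2.52 ± 0.13 percent with ZLN005 and 2.58 ± 0.0053 percent with GW501516. Of the 13, 5 share over 95 percent of their 75-base windows with nuclear copies, and ND4 (61.5 percent), COX1 (39.8 percent), ND2 (5.71 percent) and ND5 (1.66 percent) share fewer. No annotated transcript covers the nuclear counterpart of ATP8, so its count is uncertain as well as those of these 9 genes. Nuclear genes of complexes II to IV were higher for 26 of 26 over ZLN005 (26 adjusted over the list alone, median 1.16, adjusted p = 1.1e-15, but adjusted p = 0.124 with an estimated correlation). Over GW501516 they were higher for 25 (median 1.01, adjusted p = 3.6e-12, but adjusted p = 0.193 with an estimated correlation). Cycs was higher by 1.98 ± 0.05 and 1.72 ± 0.05. ATP synthase genes were higher for all 16 in both comparisons (medians 1.07 and 0.91, adjusted p = 1.1e-10 and 8.1e-09, but adjusted p = 0.124 and 0.193 with an estimated correlation). The tricarboxylic acid cycle list was higher for 24 and 23 of 26 (medians 1.04 and 0.93, adjusted p = 7.8e-13 and 1.1e-11, but adjusted p = 0.0828 and 0.0849 with an estimated correlation). Idh2 was higher by 2.52 ± 0.07 and 2.60 ± 0.07. PPAR targets were higher in CM than with ZLN005 for 18 of 30 with 6 lower (median 0.71, the same with such genes at their bound where a group had no counts, adjusted p = 3.96e-05, but adjusted p = 0.0866 with an estimated correlation). Against GW501516 they were higher for 11 and lower for 15 (median −0.21, mean 0.12, adjusted p = 0.379). Angptl4 (−3.99 ± 0.09), Pdk4 (−2.38 ± 0.05) and, on the fatty acid oxidation list, Cpt1a (−2.04 ± 0.07) were lower in CM and Fabp3 (3.60 ± 0.07) was higher. Cholesterol synthesis genes were higher in CM than with ZLN005 for 18 of 23 with 3 lower (median 0.86, adjusted p = 1.1e-05, but adjusted p = 0.146 with an estimated correlation). Insig1 was higher by 1.64 ± 0.04. Against GW501516 they split, 4 higher and 8 lower (adjusted p = 0.342).

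Proliferation, p53 and interferon genes also parted CM from the treated iCM. Ccnb1, cyclin B1, was higher in CM by 3.16 ± 0.10 over ZLN005 and 3.05 ± 0.10 over GW501516, and 31 of 32 cell cycle genes were higher with 1 lower in both comparisons (medians 2.38 and 2.32, adjusted p = 3.4e-21 and 1.3e-19, but adjusted p = 0.0828 and 0.0849 with an estimated correlation). Targets of p53 were lower in CM for 19 of 20 with 1 higher in both comparisons (19 and 1 adjusted over the list alone, medians −1.36 and −1.22). These calls held with an estimated correlation (adjusted p = 7.8e-13 and 6.2e-11, and 0.0229 and 0.0296). Cdkn1a, the cell cycle inhibitor p21, stood at 162 ± 1.4 CPM in CM against 765 ± 21 with ZLN005 (−2.24 ± 0.04), Fas at 11.3 ± 0.40 against 117 ± 1.8 (−3.38 ± 0.05), and Plk2 was the higher member (2.51 ± 0.05). All 29 interferon response genes were lower in CM than in either treated group (29 adjusted over the list alone, medians −6.35 and −6.71, the same with such genes at their bound where a group had no counts, adjusted p = 2.1e-70 and 1.5e-75, but adjusted p = 0.0661 and 0.0634 with an estimated correlation). Oas2, an antiviral nucleotide synthetase, had no counts in CM and was at least 3206-fold lower than with ZLN005, where it stood at 110 ± 3.1 CPM, and at least 4060.4-fold lower than with GW501516. Mx1, another antiviral gene, was at least 443-fold and 882-fold lower, Oas1g at least 613-fold and 842-fold, and Col22a1, a collagen gene, at least 407-fold and 1098-fold. Scg2 was lower by −11.82 ± 0.25 and −12.13 ± 0.25, Kcnc4 by −11.13 ± 0.20 than with ZLN005, and Ifi44 by −11.33 ± 0.26 than with GW501516. Fibroblast genes split, with 17 higher and 15 lower of 34 in CM than with ZLN005 (adjusted p = 0.563), Lum at 3.42 ± 0.07 and Mfap4 at −1.75 ± 0.06. Endothelial genes were higher in CM for 16 of 19 with 1 lower in both comparisons (16 and 1 adjusted over the list alone, medians 1.89 and 1.84, the same with such genes at their bound, adjusted p = 0.0348 and 0.0972, but adjusted p = 0.240 and 0.441 with an estimated correlation). Smooth muscle and pericyte genes were higher for 8 and 9 of 14 with 3 lower (8 and 9 with 3 adjusted over the list alone, medians 1.25 and 1.33, adjusted p = 0.00357 and 0.00932, but adjusted p = 0.447 and 0.607 with an estimated correlation). The macrophage list held 0.0148 ± 0.00014 percent of the counts of CM. CM differed from ZLN005-treated iCM in 10682 of 15740 genes (5382 higher) with 23 lists called, and from GW501516-treated iCM in 10573 (5300 higher) with 17 lists called. For the called lists named here with no separate count, the numbers of higher and lower genes were the same adjusted over the list alone. With an estimated correlation only the p53 list held against ZLN005 and the p53 and sarcomere lists against GW501516.

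CM was also set against the 2 groups without compound. Against CF, Bmp10 was at least 6784-fold higher in CM, Nppb higher by 10.70 ± 0.10 and Smpx, a small muscle protein, by 9.82 ± 0.08, and Oas2 was at least 1041-fold lower. All 36 sarcomere genes were higher in CM than in CF (36 adjusted over the list alone, median 7.36, adjusted p = 3.7e-139, and 0.00389 with an estimated correlation). So were 34 of 36 calcium handling genes with 1 lower (median 4.69, adjusted p = 5.2e-50, and 0.00700 with an estimated correlation). Of the fibroblast genes 28 of 34 were lower with 3 higher (median −1.49, adjusted p = 1.5e-19, but adjusted p = 0.140 with an estimated correlation). Interferon, cell cycle and p53 lists also separated CM from CF, so those differences were not particular to the iCM. All 29 interferon response genes were lower (29 adjusted over the list alone, median −4.36, the same with such genes at their bound, adjusted p = 8.2e-36, but adjusted p = 0.0862 with an estimated correlation). Of 32 cell cycle genes 31 were higher and 1 lower (31 and 1 adjusted over the list alone, median 1.06, adjusted p = 2.3e-05, but adjusted p = 0.267 with an estimated correlation), and of 20 p53 targets 17 were lower and 2 higher (17 and 2 adjusted over the list alone, median −0.95, adjusted p = 4.2e-05, but adjusted p = 0.0585 with an estimated correlation). Scd1 differed by 0.06 ± 0.06 between CM and CF (adjusted p = 0.40), and by 0.16 (adjusted p = 0.0160) without CF replicate 2. Against DMSO-treated iCM, Myh6 was higher by 4.72 and Csrp3 by 4.55 in CM, and 35 of 36 sarcomere genes were higher (median 3.07, adjusted p = 1.0e-63, and 0.0191 with an estimated correlation). In total 11131 genes differed between CM and CF (5433 higher) and 10976 between CM and DMSO-treated iCM (5360 higher).

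To place the iCM groups between both reference cell types, each library was projected on the axis from the CF mean, at 0 percent, to the CM mean, at 100 percent, over 15737 genes without the 3 transgenes. iCM with DMSO lay at 22.8 ± 0.28 percent, with ZLN005 at 36.0 ± 0.060 percent and with GW501516 at 33.5 ± 0.091 percent (SD, n = 2). The differences from DMSO were 13.2 and 10.6 percentage points, and GW501516 lay −2.53 points from ZLN005. Each exceeded the spread between replicates of the iCM groups, and the 2-sided exact permutation p was 0.333, the smallest that 6 splits of 4 libraries can give. The 2 CF libraries, whose counts of macrophage genes differed, lay at −4.34 and 4.34 percent, farther apart than the compounds. With the CF replicate 1 set left out the 3 iCM groups lay at 26.2, 31.0 and 29.0 percent. Genes at least 4-fold higher in CM than in CF, 1103 in number, rose with ZLN005 (237 up and 70 down, median 0.18, adjusted p = 5.2e-09, and 0.000655 with an estimated correlation). They also rose with GW501516 (210 up and 66 down, median 0.14, adjusted p = 2.8e-06, and 0.000971 with an estimated correlation). Without 1 of the 4 libraries compared, the calls were 161 to 168 up and 28 to 37 down with ZLN005, and 148 to 155 up and 30 to 36 down with GW501516. The 1307 genes at least 4-fold higher in CF fell with ZLN005 (392 down and 66 up, median −0.44, adjusted p = 7.3e-12, and 0.0415 with an estimated correlation), and with the CF replicate 1 set left out the median was −0.18 (213 down and 78 up, adjusted p = 4.3e-06). The falls numbered 208 and 211 without DMSO replicate 1 or 2 and 147 and 148 without ZLN005 replicate 1 or 2, with medians from −0.43 to −0.46. They also fell with GW501516 (292 down and 133 up, median −0.27, adjusted p = 0.000246, but adjusted p = 0.141 with an estimated correlation). That last list call was lost with the CF replicate 1 set left out, at a median of −0.02 and adjusted p = 0.747. The balance of called genes reversed to 67 down and 78 up without GW501516 replicate 1 and to 75 down and 79 up without replicate 2, and was 105 down and 79 up or 122 down and 85 up without DMSO replicate 1 or 2, at medians from −0.26 to −0.30. For genes at least 16-fold higher in CF the medians were −1.67 with ZLN005 and −1.39 with GW501516. For genes at least 2-fold higher they were −0.16 and −0.11, so the size of the fall depended on this threshold. The CF replicate 1 set was kept at both thresholds, and how far its macrophage genes set these medians was not tested. The fixed fibroblast and matrix list had medians of −0.45 and −0.09. Between the compounds the CM-high genes were not called (median 0.05, adjusted p = 0.188), and the CF-high genes were lower with ZLN005 (median −0.17, adjusted p = 5.7e-05, but adjusted p = 0.128 with an estimated correlation).

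**Figure D3:**
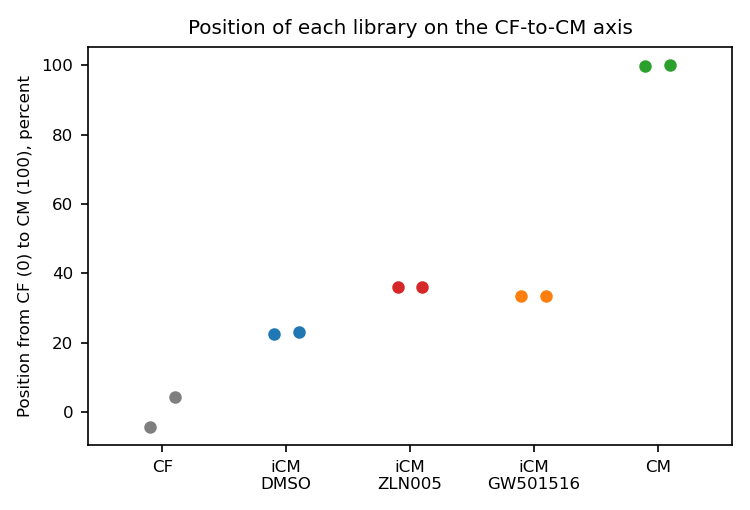
Position of each of the 10 libraries on the expression axis from the mean of CF (0 percent) to the mean of CM (100 percent), in percent; points are libraries. iCM with DMSO lie at 22.6 and 23.0 percent, with ZLN005 at 36.0 and 35.9 percent and with GW501516 at 33.4 and 33.5 percent.

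The effects of both compounds were correlated across genes, which are not independent replicates. Over 15740 genes the log2 changes with ZLN005 and GW501516 had a Pearson r of 0.716. In 100 simulations of unchanged groups with shared controls the mean was 0.469 and the maximum 0.507. Every library, those of DMSO included, was redrawn there at the DMSO mean with independent noise per gene. Differences between cultures were not simulated, so an r above that maximum does not show that the compounds caused it. With the CF replicate 1 set left out r was 0.563, against a mean of 0.468 and a maximum of 0.514 in the same simulations over those 14861 genes. The covariance was 0.383 against a simulated mean of 0.0480, a difference of 0.335. With both compounds 635 genes were higher and 743 lower, where independent lists would share 81.5 and 96.8, and part of the excess may come from the shared controls, since both compounds were set against the same 2 DMSO libraries. Opposite calls were made for 60 genes, 51 of them lower with ZLN005 and higher with GW501516. Ucp2 (−1.15 and 3.20), Fmo2 (−0.90 and 0.86) and Insig1 (−0.84 and 0.87) were among these, and Adora1 (0.83 and −0.84) went the other way. Fmo2 was chosen after its values were seen.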

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

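Genes of fatty acid synthesis and desaturation differed between the compounds when tested directly, with a median log2 change of −0.27 for ZLN005 against GW501516, and the list was lower with ZLN005 and higher with GW501516 relative to DMSO. With an estimated correlation its call with ZLN005 was lost (adjusted p = 0.0908) and that with GW501516 held (adjusted p = 0.0120). Scd2, a desaturase, differed by −1.35 ± 0.05. Genes of cholesterol synthesis differed in the same test with a median of −0.91, also lower with ZLN005 and higher with GW501516 relative to DMSO, and both calls held with an estimated correlation (adjusted p = 0.0396 and 0.0452). Insig1, a sterol sensor partner, differed by −1.71 ± 0.04.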

How the results depend on the processing

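With an absolute log2 change of at least 1 added, 1880 genes were called for iCM with DMSO against CF, 547 for ZLN005 and 508 for GW501516 against DMSO, 122 between the compounds, and 5050, 4721, 4498 and 4386 for CM against CF, DMSO, ZLN005 and GW501516. With only the 2 groups compared in the fit, ZLN005 gave 4477 genes, GW501516 4342 and the compounds 2413, and with the 3 iCM groups alone, chosen after the data were seen, 4455, 4420 and 2350. Leaving out single libraries gave 1086 to 4257 genes for ZLN005, 965 to 4227 for GW501516 and 345 to 2167 between the compounds, with the upper ends reached without a CF library. List calls with an estimated correlation numbered 2 for DMSO against CF, 3 for ZLN005, 5 for GW501516, 5 between the compounds, 1 for CM against ZLN005 and 2 for CM against GW501516. The median of CM-high genes between the compounds was 0.0518 (adjusted p = 0.0202) for genes at least 16-fold higher in CM. With ZLN005 and GW501516 the medians of CM-high genes were 0.25 and 0.26 at 16-fold and 0.09 and 0.09 at 2-fold. Those of CF-high genes were −1.67 and −1.39 at 16-fold and −0.16 and −0.11 at 2-fold, with the CF replicate 1 set kept. CF-high genes lost their calls with an estimated correlation for GW501516 (−0.268, adjusted p = 0.141) and between the compounds (−0.173, adjusted p = 0.128), and for GW501516 with the CF replicate 1 set left out (−0.0242, adjusted p = 0.747). Axis positions of DMSO, ZLN005 and GW501516 were 22.1, 35.2 and 32.9 percent with a prior count of 0.5, 23.7, 36.4 and 33.8 percent with 10, and 26.2, 31.0 and 29.0 percent without that set. ZLN005 lay at 36.4 and GW501516 at 33.9 percent over genes called in CM against CF, and ZLN005 at 36.1 percent with the transgenes kept, 35.9 percent with DESeq2 size factors, and 35.9 and 36.0 percent without its replicate 1 or 2. A block for replicate number gave 2252, 2235 and 718 genes for ZLN005, GW501516 and the compounds, but the numbers do not pair the samples, since correlations of replicate deviations between groups ranged from −0.00318 to 0.0398.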

Other observations

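Among the tests here, only the leaving out of the CF replicate 1 set, the iCM-only fit, the leaving out of CF replicates in comparisons without CF and the tests named as such below were chosen after the results were seen. Des, the muscle intermediate filament gene, rose by 5.90 ± 0.12 from CF to iCM with DMSO, and 11 of 22 skeletal muscle genes rose with 2 falls (11 and 3 adjusted over the list alone, median 1.45, adjusted p = 4.5e-05, but adjusted p = 0.249 with an estimated correlation). Tnnt3, a fast troponin, rose by 0.83 ± 0.09 with ZLN005 and 1.27 ± 0.09 with GW501516. That list had 7 rises and 1 fall with ZLN005 (9 and 1 adjusted over the list alone, median 0.35, adjusted p = 6.0e-06, but adjusted p = 0.0908 with an estimated correlation). With GW501516 it had 6 and 2 (7 and 3 adjusted over the list alone, median 0.35, adjusted p = 8.7e-05, but adjusted p = 0.126 with an estimated correlation). Cytosolic ribosomal protein genes fell from CF to iCM, 35 of 42 (35 adjusted over the list alone, median −0.29, adjusted p = 0.000126, but adjusted p = 0.680 with an estimated correlation), Rps4x by −0.48 ± 0.05. With GW501516, 6 of them rose (12 adjusted over the list alone, median 0.14, adjusted p = 0.000248, but adjusted p = 0.603 with an estimated correlation). Smooth muscle and pericyte genes had 7 rises and 4 falls of 14 from CF to iCM (7 and 4 adjusted over the list alone, median 0.74, adjusted p = 0.0137, but adjusted p = 0.680 with an estimated correlation), with Cspg4 up by 2.96 ± 0.13. With ZLN005, 8 of them fell and 2 rose (8 and 2 adjusted over the list alone, median −0.47, adjusted p = 0.00395, but adjusted p = 0.397 with an estimated correlation), and the pericyte gene Rgs5 changed by −1.93 ± 0.22. Endothelial genes had 10 falls and 1 rise of 19 from CF to iCM (11 and 1 adjusted over the list alone, median −1.17, and −1.07 with such genes at their bound, adjusted p = 0.158), Tek by −1.44 ± 0.14.

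Btg2, a p53 target, rose by 0.81 ± 0.04 with ZLN005, where p53 targets had 8 rises and 2 falls of 20 (12 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.000349, but adjusted p = 0.0618 with an estimated correlation). Cxcl12, a stromal chemokine, changed by −0.90 ± 0.06 with ZLN005, and the inflammatory list had 7 falls and 2 rises of 22 (9 and 4 adjusted over the list alone, median −0.18, and −0.09 with such genes at their bound, adjusted p = 0.0202, but adjusted p = 0.301 with an estimated correlation). Egln3, a hypoxia target, rose by 1.11 ± 0.06 with ZLN005, with 4 rises and 2 falls of 15 hypoxia genes (7 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.0202, but adjusted p = 0.228 with an estimated correlation). Msln, a mesothelial gene, rose by 0.82 ± 0.07 with ZLN005, with 5 rises of 13 epicardial genes (5 up and 1 down adjusted over the list alone, median 0.12, adjusted p = 0.00395, but adjusted p = 0.280 with an estimated correlation). With GW501516 that list had 4 rises (5 adjusted over the list alone, median 0.21, adjusted p = 0.0204, but adjusted p = 0.422 with an estimated correlation). Cat, catalase, rose by 0.51 ± 0.05 with GW501516, with 6 rises and 1 fall of 23 antioxidant genes (7 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.0408, but adjusted p = 0.358 with an estimated correlation, and adjusted p = 0.0641 without DMSO replicate 1 and 0.0820 without GW501516 replicate 1). The mitochondrial ribosome list of 47 had a median of 0.07 with ZLN005 (adjusted p = 0.0483, but adjusted p = 0.481 with an estimated correlation, and adjusted p = 0.178 without DMSO replicate 1 and 0.104 without ZLN005 replicate 1). Stress response, Schwann and adipocyte lists were not called with ZLN005 (adjusted p = 0.482, 0.132 and 0.302), with Ddit3 at 0.59 ± 0.07 and Mbp at −0.91 ± 0.15.

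The tests of fewer macrophages and of culture-to-culture variation were chosen only after the fall of macrophage genes was seen. Macrophage genes such as Csf1r and Spp1 fell with both compounds. Fewer macrophages would lower the other genes of the CF replicate 1 set as well, whose medians were −0.958 and −0.964 against a predicted −1 or less, but that set also holds genes of other cell types, so this cannot be told apart from regulation within cells. Library depth was excluded, as the median stayed at −2.40 or below after thinning. Replicate CF libraries differed by 2.56 in the list median log2 CPM. On the same measure the groups stood at 4.71 with DMSO, 1.66 with ZLN005 and 1.65 with GW501516. Both falls thus exceeded the CF difference on that measure. The test itself set the CF difference against the smaller median log2 change of the list, an absolute 2.40 with GW501516. The CF difference was 107 percent of it, so the prediction for variation between cultures was met. Replicates of DMSO, ZLN005 and GW501516 differed by 0.0556, 0.0501 and 0.0485. Variation between cultures was not excluded as a cause of the fall. The small replicate differences cannot decide this, because the labels do not say whether the libraries of a group came from separate cultures. An action of the compounds on macrophages is an untested hypothesis.

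The test of transgene expression was chosen only after the rise of sarcomere genes was seen. Csrp3, Myh6 and Actn2 rose with both compounds. The CF replicate 1 set held at most 0.857 percent of the counts of a DMSO library. Loss of these counts alone would raise all other genes by 0.0124 log2 units. Dilution by macrophage RNA as a whole was not excluded, because the set leaves out genes that macrophages share with other cells. A single unusual DMSO library was excluded, since the sarcomere median kept 98.4 percent of its value. More transgene expression was not excluded. The larger median rise of Mef2c, Gata4 and Tbx5 was 0.100. Gata4 was called higher, by 0.29 with ZLN005 and 0.24 with GW501516, while Mef2c and Tbx5 were not called with either compound. That test cannot decide, because the counts do not separate the transgenes from the endogenous genes. A shift of the iCM toward muscle expression is a hypothesis that these tests leave open. The compound effect itself may still include differences between cultures or in RNA quality, neither of which was excluded.

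The tests of short transcripts and of copies with ATP8 set aside were chosen only after the low counts of some mitochondrially encoded genes were seen. COX2, COX3, ATP6, ND4L and ND3 had at most 1.25 percent of the counts per kilobase of COX1 and share over 95 percent of their windows with nuclear copies, and ATP8, for which no annotated transcript covers the nuclear counterpart, had 0.0527 percent. Reads shared with nuclear copies stay open, at a rank correlation of −0.720 over 12 genes, and cannot be told apart from other causes over all 13 (−0.430), since ATP8 was in effect not searched. Loss of short transcripts was excluded for ND4L and ATP8, which lay 31.8-fold below ND4 and 11.8-fold below ATP6 on the same messenger RNA. COX2, COX3 and ATP6 are longer than ND6 yet lay at least 14.5-fold below it in every library. That test cannot decide, because the strand setting is not known and ND6 counts may hold reads of the opposite strand. For ND3 the loss of short transcripts cannot be told apart, as the shorter ND4L had 3.58 times its counts per kilobase and is itself low. No biological explanation was tested.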
